A study of Felis catus with 4 samples.

How the data were processed

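RNA was sequenced from 4 feline cell cultures: 2 lines of induced pluripotent stem cells (iPSC) and 2 lines of mesenchymal stromal cells (MSC) derived from such cells. Per the labels' protocols, total RNA was isolated with a column kit, 1.3 µg was put into each library, and libraries were made with a SMARTER mRNA kit. Each library was assigned to its group from its GEO title, and each column of the table was matched to its library by the name in the sample description. No column of the table was left unused (0 unused columns).

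The authors deposited one table of raw read counts for 26681 cat Ensembl gene identifiers, with one column per library, per the file headers and the whole-number values. Replicates were not pooled. The aligner, the counting tool and the use of strand are not given in the sources used here. The submitters' processing notes name the builds GRCm38 and mm10, which are mouse assemblies, while every identifier in the deposited count table carries the cat prefix. The build behind the counts is therefore uncertain, and no coordinates are given. Reads shared between near-identical or overlapping genes cannot be traced from the table. All rows carried a gene identifier (0 rows without one). The series' design text names DESeq2 as the differential test.

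The deposited counts were not paired with gene symbols, and none of the 39307 rows of the gene reference used here carries an Ensembl identifier (0 rows). The 22 gene lists fixed before the data were examined (pluripotency, stromal surface markers, extracellular matrix, epithelial and mesenchymal genes, contractile genes, signalling, secreted factors, interferon response, cell cycle, senescence, glycolysis, HOX clusters and markers of other cell types) hold 615 symbols, of which 0 could be matched to a row. Their counts and set tests were therefore not run, and no gene is named by symbol. The rule fixed for named genes took the 6 genes with the largest fold change in each direction that passed the threshold, had a symbol, had a mean of at least 10 CPM (counts scaled to library size) in the higher group, and had every library of one group above every library of the other. Without symbols that condition was dropped, the parts of the rule that list genes by symbol could not be used, and only the first 2 identifiers in each direction are given.

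The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3) on the counts as deposited, with TMM normalization and the filterByExpr filter, which kept 12728 genes of the 17191 with at least 1 count. The model held the group alone, fold changes are MSC minus iPSC on the log2 scale, and genes with a two-sided Benjamini-Hochberg adjusted p below 0.05 were called. The standard error (SE) of a log2 fold change was back-calculated as its absolute value over the square root of the F statistic. CPM values use TMM library sizes over the genes kept by the filter, except in counts of genes at a CPM minimum in one group and at 0 in the other, which use library totals. Where both libraries of a group had 0 counts, the fold is given as a lower bound against 3 counts over that group. The floors cover counting error only, and reads without molecular identifiers are not independent molecules. Intervals given for medians over genes are 95% bootstrap intervals from 2000 resamples of the genes. They measure the uncertainty of the median from the sampling of genes, and not the spread among genes or between lines.

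Library totals were 13891598 counts for iPSC line 1, 2268351 for iPSC line 2, 20395499 for MSC line 1 and 21299755 for MSC line 2. A floor of 3 counts corresponds to 0.204, 1.39, 0.147 and 0.143 CPM in the same order. To compare libraries at one depth, counts were thinned binomially to the total of the shallowest library. Replicates were checked for double deposition with a chi-square over genes with at least 20 counts per pair. The statistic per degree of freedom was 11.4 for the iPSC pair and 79 for the MSC pair, far above the value near 1 that sampling noise gives, so each library was counted once.

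The fit was tested on simulated data with the means, library sizes and dispersions of these libraries (12728 genes, 50 changed at each size). It recovered 40% of genes changed 2-fold, 80% changed 4-fold, 88% changed 8-fold and 100% changed 32-fold. At 8-fold it recovered 22 rises and 22 falls. The changed genes were drawn from all levels, and each change was split evenly around a mean pooled over the libraries. In the real data, 128 of 146 falls and 17 of 19 rises of at least 8-fold were in the class of genes with the lowest mean log2 CPM. Recovery in that class alone was not measured. Of 168 genes called in the simulation, 14 (8.33%) were unchanged by construction, against a nominal 5%.

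The alternatives fixed before the data were examined were DESeq2 size factors, upper-quartile factors, the DESeq2 Wald test (DESeq2 1.42.0), limma-voom (limma 3.58.1), no filter on low counts, a minimum of 1 CPM in 2 libraries, a test against a fold change of 2 (glmTreat), the replicate number as a block, and leaving out each library. Thinning to equal depth and the counts of genes changed at least 8-fold were added after seeing the data. Lines of both groups carry the number 1 or 2. The series' design text relates the MSC to the iPSC they came from, but no label states that an MSC line came from the iPSC line of the same number, so the main model has no block. Figures were drawn with matplotlib 3.10.9.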

Results

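Gene expression was profiled by RNA sequencing in cat induced pluripotent stem cells, which are somatic cells returned to a state able to form all tissues, and in mesenchymal stromal cells, which are adherent fibroblast-like cells, obtained from such iPSC by differentiation. The iPSC had been made with Sendai virus, an RNA virus used to deliver reprogramming factors without integration into the genome. The 2 iPSC lines were at passage 15 and grew in 15% serum with leukemia inhibitory factor at 1000 IU/mL and basic fibroblast growth factor at 6.0 ng/mL. The 2 MSC lines were at passage 3 and grew in 30% serum. Cell type therefore goes together with passage and medium in these libraries. The total count was 13891598 for iPSC line 1, 2268351 for iPSC line 2, 20395499 for MSC line 1 and 21299755 for MSC line 2. At least 1 count was found for 15895, 13330, 15443 and 15460 genes, respectively. Genes are given by Ensembl identifier because the deposited table carries no symbols, and the functions of the changed genes are not described here.

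The cells of each type resembled each other more than cells of the other type. Over the 12728 genes tested, log2 CPM values (counts scaled to library size) correlated at Pearson's r = 0.976 between the MSC lines and 0.949 between the iPSC lines, and at 0.912 to 0.931 between an iPSC and an MSC library. These correlations are across genes, which are not independent replicates. When all libraries were thinned to the depth of the shallowest, the SD of the log2 ratio over genes was 0.582 for the MSC pair, 0.621 for the iPSC pair and 0.808 to 0.901 for pairs across types. The first principal component held 62.3% of the variance and placed the iPSC lines at -38.91 and -59.91 and the MSC lines at 46.53 and 52.29. The second held 27.3% and separated iPSC line 1 from iPSC line 2, at 48.88 and -40.17. Both components were computed at full depth, where the iPSC lines differ in total count, so depth and line cannot be told apart on the second. At equal depth the correlations were 0.967 for the MSC pair, 0.961 for the iPSC pair and 0.917 to 0.934 across types.

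The comparison of MSC with iPSC addressed which genes change as pluripotent cells become stromal cells. In MSC, 402 genes were higher and 365 genes were lower than in iPSC, while 11961 genes did not pass the threshold. The genes higher in MSC changed moderately, with a median log2 fold change of 1.44 (interquartile range 1.10 to 1.99). The genes lower in MSC changed further, with a median decrease of 2.30 on the log2 scale (interquartile range of the decrease 1.38 to 4.28). In each of these 767 genes, both MSC libraries lay on the same side of both iPSC libraries (402 of 402 and 365 of 365). Chance gives this separation in 33.3% of genes, and the choice of genes by the same test favours it. Genes were called with edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p below 0.05, with n = 2 lines per group, and 2793 genes had an unadjusted p below 0.05. The calls were 94 higher and 132 lower in MSC without iPSC line 1, 259 and 415 without iPSC line 2, the shallowest library, and 768 and 566 without MSC line 1. Tested against a fold change of 2, 35 genes were higher and 138 lower in MSC. Without a filter on low counts 1042 were higher and 820 lower. Which direction had more genes also changed with the normalization, with 356 higher and 375 lower under DESeq2 size factors.

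Large changes were mainly losses in the stromal cells. At least 8-fold differences were fitted for 146 genes lower in MSC and for 19 genes higher in MSC. Between 2-fold and 4-fold the order in the main fit was the other way, with 234 genes higher and 128 lower in MSC. The 146 strongly lower genes had a median of 6.84 CPM in iPSC and 0.206 CPM in MSC. In 31 of them both MSC libraries had 0 counts, so that a fold can only be bounded, at a median of at least 44.3-fold and a range of at least 13.9-fold to at least 777-fold, against 3 counts over both MSC libraries. The median bound was 19.1-fold without iPSC line 1, and 22.5-fold and 21.8-fold without MSC lines 1 and 2, where the floor rests on a single library. Differences over 64-fold were fitted for 62 genes lower in MSC, and 41 reached that size when the genes at 0 were set to their bound. The 19 strongly higher genes had a median of 0.462 CPM in iPSC and 6.57 CPM in MSC, and in 1 of them both iPSC libraries had 0 counts. The size of the strongly lower group depended on single libraries: 246 genes without iPSC line 2 and 55 without iPSC line 1, against 31 and 21 strongly higher genes in the same fits. Without MSC line 1 there were 31 strongly higher and 161 strongly lower genes, and with libraries thinned to equal depth 14 and 67. Without a filter on low counts there were 36 and 288, and tested against a fold change of 2, 7 and 104.

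**Figure D1:**
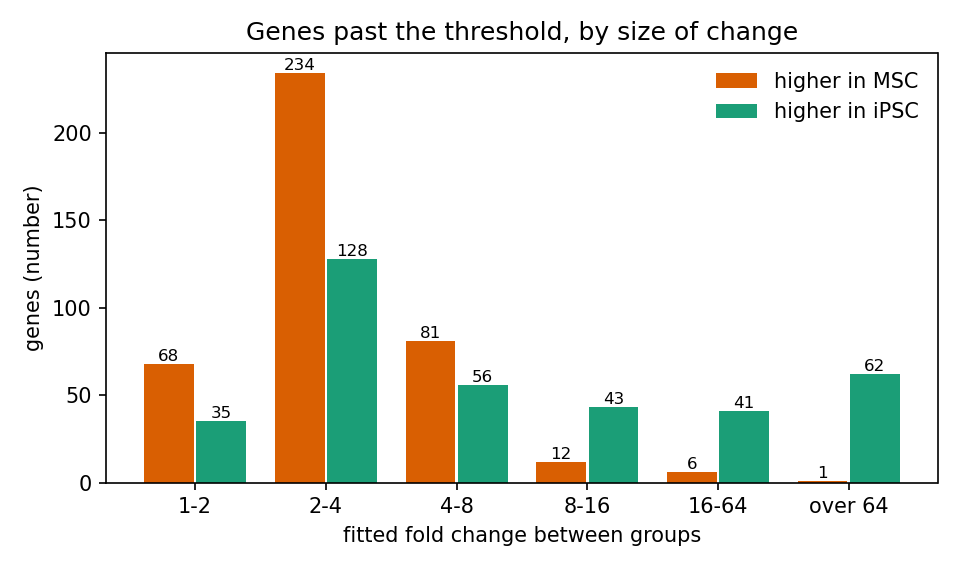
Number of genes past the threshold in the main fit (vertical axis) by the fitted fold change between groups (horizontal axis). Genes higher in MSC and genes higher in iPSC are shown separately. Up to 8-fold the genes higher in MSC are the more numerous in each class (81 against 56 at 4-fold to 8-fold), and above 8-fold the genes higher in iPSC are (62 against 1 over 64-fold, of which 41 and 0 remain with genes at 0 counts set to their lower bound).

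The strongly lower genes made up 0.657% ± 0.203 (SD, n = 2) of the CPM in iPSC and 0.0199% ± 2.27e-04 (SD, n = 2) in MSC. All 365 genes lower in MSC together held 2.93% ± 0.111 (SD, n = 2) of the CPM in iPSC and 0.934% ± 0.00192 (SD, n = 2) in MSC. The 402 genes higher in MSC held 1.58% ± 0.102 (SD, n = 2) in iPSC and 3.84% ± 0.453 (SD, n = 2) in MSC. Because the genes were chosen by their difference, these shares describe the size of the change and are not a separate test. The 10 most abundant genes took 14.3% ± 1.97 (SD, n = 2) of all counts in iPSC and 13.5% ± 1.42 (SD, n = 2) in MSC, a difference smaller than the spread between lines. In the group where they were higher, 63 of the 146 strongly lower genes were over 10 CPM and 13 over 100 CPM. Of the 19 strongly higher genes, 8 were over 10 CPM and 0 over 100 CPM in MSC.

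Among genes past the threshold with at least 10 CPM in the higher group, the identifiers with the largest decrease in MSC were ENSFCAG00000022639 and ENSFCAG00000044201. ENSFCAG00000022639 had 1382 and 41 counts in iPSC lines 1 and 2 and 0 counts in both MSC lines. Its level of 56.4 ± 52.9 CPM (SD, n = 2) in iPSC was at least 777-fold higher than in MSC, with an adjusted p of 0.00229 by edgeR, and the iPSC lines themselves differed 4.95-fold. The bound was 261-fold without iPSC line 1, 1293-fold without iPSC line 2, 394-fold without MSC line 1 and 383-fold without MSC line 2. ENSFCAG00000044201 had 467 and 41 counts in iPSC and 0 in both MSC lines. Its iPSC level of 25.3 ± 9.02 CPM (SD, n = 2) was at least 349-fold higher than in MSC (edgeR adjusted p = 0.000184), and the bound was 177-fold without MSC line 1 and 172-fold without MSC line 2. The identifiers with the largest increase at that level were ENSFCAG00000045309 and ENSFCAG00000046126. ENSFCAG00000045309 rose from 0.672 ± 0.297 CPM in iPSC to 14.1 ± 7.12 CPM in MSC (SD, n = 2), with a log2 fold change of 4.12 ± 0.56 (SE) and an edgeR adjusted p of 0.00526. Its counts were 13 and 1 in the iPSC libraries and 184 and 401 in the MSC libraries, and its log2 fold change was 4.90 without iPSC line 1 and 3.48 without MSC line 2. ENSFCAG00000046126 rose from 2.87 ± 1.17 to 37.5 ± 18.1 CPM (SD, n = 2), with a log2 fold change of 3.95 ± 0.46 (SE) and an edgeR adjusted p of 0.00278. Its counts were 30 and 8 in iPSC and 1025 and 517 in MSC, and its log2 fold change was 3.34 without iPSC line 1 and 3.32 without MSC line 1.

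Differences between lines of one cell type gave the background for these changes. At equal depth, with at least 20 counts in the higher library, 30 genes were over 8-fold higher in iPSC line 1 than in iPSC line 2 and 6 were over 8-fold lower. Between the MSC lines the numbers were 7 and 6. Across cell types, iPSC line 1 had 101 genes over 8-fold above MSC line 1 and 125 above MSC line 2, against 21 and 50 genes in the opposite direction. For iPSC line 2 the difference between directions was smaller, with 61 and 56 genes above MSC lines 1 and 2 and 30 and 47 below them. At this depth, 7 genes had at least 10 CPM in both iPSC libraries and 0 counts in both MSC libraries, against 2 genes at full depth, and 0 genes showed the reverse at either depth. The number of genes detected at equal depth was 13627 ± 420 (SD, n = 2) in iPSC and 13264 ± 4.24 (SD, n = 2) in MSC, and the difference was smaller than the spread between the iPSC lines.

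**Figure D2:**
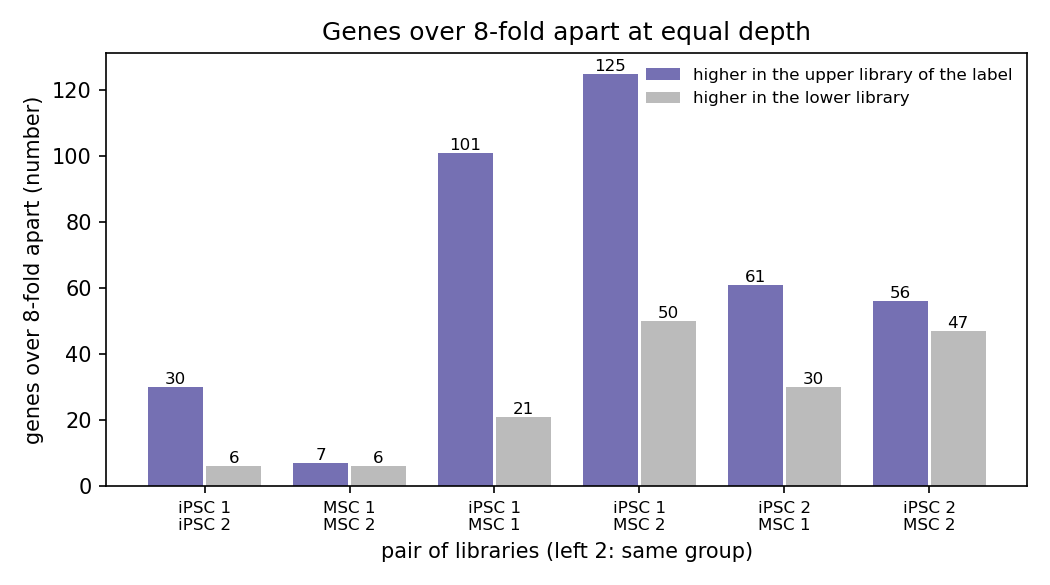
Number of genes over 8-fold apart (vertical axis) in each pair of libraries (horizontal axis), all thinned to the depth of the shallowest and counted with at least 20 counts in the higher library. Purple bars count genes higher in the library named on top and grey bars those higher in the library named beneath it. Pairs within a cell type gave 6 to 30 genes per direction and pairs across cell types 21 to 125.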

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

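Thinning to equal depth and all counts of genes changed at least 8-fold were chosen only after the result was seen. The counts were within 1.5 times of 402 genes higher and 365 genes lower in MSC under DESeq2 and upper-quartile factors, the DESeq2 Wald test, limma-voom and a minimum of 1 CPM in 2 libraries. The direction with more genes was not stable among them. With DESeq2 size factors 356 were higher and 375 lower in MSC, and with upper-quartile factors 343 and 358. The numbers were 369 and 420 in limma-voom, 337 and 360 with the 1 CPM minimum, and 496 and 452 in the DESeq2 Wald test. Of the 767 genes, 732 were also called by the DESeq2 Wald test and 686 by limma-voom. Without a filter, 1042 were higher and 820 lower in MSC, with 36 and 288 of these at least 8-fold. Against a fold change of 2, 35 were higher and 138 lower, with 7 and 104 at least 8-fold, so that the share higher in MSC was 20.2% in place of 52.4%. Thinned to equal depth, 265 were higher and 212 lower in MSC, with 14 and 67 at least 8-fold. Over 10 such thinnings, 250 to 356 were higher (median 294) and 206 to 269 lower (median 246), so that the medians were within 1.5 times of the counts at full depth, and 10 to 20 and 61 to 69 were at least 8-fold. Leaving out single libraries gave 94 to 768 genes higher and 132 to 566 lower in MSC, and 15 to 31 and 55 to 246 at least 8-fold. The share higher in MSC was 41.6% without iPSC line 1 and 38.4% without iPSC line 2. With an arm of 1 library, that library is assumed to vary like the others. With the replicate number as a block, 849 were higher and 686 lower in MSC, and 31 and 153 at least 8-fold. Deviations of same-numbered lines from their group means correlated at 0.238 across genes, from 2 numbers only, and the labels do not state that the numbers pair the lines. None of the 767 genes changed sign in any alternative that tested it, and the 4 printed identifiers kept their direction in all 13 alternatives. These outcomes were largely fixed by the choice of genes, as both MSC libraries lay on the same side of both iPSC libraries in each. The identifiers had adjusted p of 0.0013 to 0.0432 in limma-voom. Without a filter, the edgeR adjusted p of ENSFCAG00000022639 was 1.25e-105, against 0.00229 in the main fit. With n = 2 lines per group, a value this small is not a credible measure against the variation between lines. The counts without a filter need the same caution. The causes of the differing counts were not tested further. The alternatives planned for normalized values were not run because the table holds counts, and those for gene lists were not run because it carries no symbols. Depth limits iPSC line 2 most, where 1 count is 0.462 CPM.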

Other observations

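The 365 genes lower in MSC were also unequal between the iPSC lines. Of them, 236 were higher in iPSC line 1 and 129 in iPSC line 2, with a median log2 ratio of line 1 to line 2 of 0.22 (95% bootstrap interval over genes 0.16 to 0.34). Among the 146 genes at least 8-fold lower in MSC, 132 were higher in line 1, with a median of 0.95 (0.75 to 1.27), which is 1.93-fold. The 11961 genes not past the threshold had a median of 0. Between the MSC lines, 297 of the 402 genes higher in MSC were higher in line 2, with a median log2 ratio of line 1 to line 2 of -0.24 (-0.29 to -0.20). These intervals treat genes as independent, which they are not, and compare single libraries.

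All patterns weighed here were noticed in these data. The tests of equal depth and of stromal cells in the iPSC cultures as causes of the excess of large decreases, of stromal cells in the iPSC line 2 culture and its low depth, and of other splits of the libraries were chosen after the values had been seen.

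Large decreases outnumbered large increases in MSC, with 146 against 19 genes at 8-fold, 55 against 21 without iPSC line 1 and 246 against 31 without iPSC line 2. A lower depth of the iPSC libraries could hide rises from low levels, but over 10 thinnings to equal depth the ratio of falls to rises of at least 8-fold among all genes tested was 3.0 to 6.0 (median 3.89), against 4.62 at full depth, which argues against low depth as the whole cause. Among genes past the threshold there were 61 to 69 falls and 10 to 20 rises at equal depth, a smaller excess than the 146 against 19 at full depth. A cap on the rises from MSC-like cells already in the iPSC cultures stays open, as the level in iPSC of the genes at least 4-fold higher in MSC, a median of 18.1% of their MSC level, is set by their choice by fold, and without gene symbols no marker could test it. A difference between the cell types themselves, which the design names, also stays open and untested.

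A candidate explanation for the lower level in iPSC line 2 of the genes that fall in MSC is a different state of that line, which was not tested and stays open. For MSC-like cells in the iPSC line 2 culture, the shift of 0.22 needs 19.0% of MSC RNA. That share predicts a median log2 ratio of -0.40 for the 402 genes higher in MSC. The genes at least 8-fold lower in MSC need 53.1%, which predicts -0.92. The observed median was 0.05 (-0.01 to 0.08), but the fit that called the 402 genes includes line 2 and disfavours genes raised there. Genes higher in MSC called without line 1 had a median of 0.54 (0.36 to 0.74). That fit has line 2 as its only iPSC library, so it favours genes low there and a positive ratio. The ratio was not measured for genes higher in MSC called without line 2. The choice of genes thus moves this median, and MSC-like cells in line 2 stay open. Low depth of iPSC line 2 cannot be told apart, since genes called anew in 10 thinnings to one total had medians of 0.10 to 0.16, with lower interval ends of 0.00 to 0.07. The 365 genes called at full depth kept a median of 0.22 (0.15 to 0.27) in a single thinning. Those at least 8-fold lower in MSC kept 0.89 (0.64 to 1.14). Thinning left the counts of line 2 as they were and drew line 1 down at random, which keeps its average level. The values thus show only that the ratio did not come from the unequal totals. They cannot show what low depth did to line 2. The genes were chosen at full depth, so an effect of depth through their choice stays open. The choice of genes by a fit that weights the deeper line 1 also stays open for the called genes as a whole, since genes called without line 1 gave 0.17 with an interval across 0 (-0.05 to 0.27). Genes lower in MSC called without line 2 had a median of 0.65 (0.54 to 0.75), so the choice moves this median. For genes at least 8-fold lower in MSC, that choice is argued against only as the whole cause. Such genes called without line 1 still had a median of 0.48 (0.36 to 0.65). With all libraries it was 0.95, so the choice may account for part of the shift.

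The grouping by cell type gave 767 genes past the threshold in edgeR. The other 2 splits of the 4 libraries into pairs gave at most 1, and only 1 of 3 splits, the real one, gave as many. Each of those other splits put 1 iPSC and 1 MSC library in both arms. The difference between cell types then counted as spread within the arms, which by itself keeps the calls low. The numbers from these splits are therefore no measure of what chance gives. With 3 splits a share under 0.05 cannot be reached.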
